A study of Homo sapiens with 21 samples.

How the data were processed

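RNA of LNCaP cells was measured in 21 libraries, 15 of a time course and 6 of a knockdown, with 3 per group; the labels state that cells were cultured and treated in triplicates. Per the labels, the authors made stranded libraries of total RNA after depletion of ribosomal RNA, and their processing notes name TopHat2 2.1.1, featureCounts 1.6.0 and GRCh38. The deposited values are counts of reads per gene model, one library per file, with no normalization. The annotation, the counting options and the strand setting are not given in the sources used here. Each file holds 64595 gene models: 60564 with Ensembl identifiers, 4030 with identifiers starting in XLOC and 1 named PROCA11. Symbols came from a name table (60295 models) and GENCODE 29 (250), and 19 Ensembl models stayed unnamed. Positions are those of GENCODE 29 on GRCh38; the XLOC models and PROCA11 have none. Whether reads shared by overlapping or near-identical genes count under each is not given in the sources used here. In all, 18 of 29192 models with at least 100 reads equal another model in every library.

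The 10 most abundant models took 46.6% to 82.4% of the time course counts and 6.87% to 7.20% of the knockdown counts. TMM factors (which scale libraries for composition) ran from 0.313 to 1.70 in the time course. Floors of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules.

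Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM, a quasi-likelihood fit, Benjamini-Hochberg adjustment over all genes tested, and a call at adjusted p under 0.05. One fit of the 5 groups served the time course (29023 genes, 10 residual degrees of freedom), and a separate fit the knockdown (22465 genes, 4 degrees of freedom). Standard errors of log2 fold changes are the fold change divided by the square root of F, which is approximate. Each time was compared with day 0, which the series names as its reference, then 1 month with 15 days, 3 months with 1 month, and 6 months with 3 months and with 15 days. One F test covered all 5 times. Comparisons with day 0 share their control libraries. The siPOOL was compared with the scramble.

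Before the data were examined, 20 gene lists, the comparisons, the tests and the rule for naming genes were written down. Lists were tested with camera in limma 3.58.1, at a preset correlation between genes of 0.01 and with the correlation estimated, and adjusted over the 20 lists of a comparison. Named genes were called, had a symbol, averaged at least 5 CPM in the higher group and had all 3 libraries of one group above all 3 of the other; list members were named by smallest adjusted p. List means over time used log2 CPM with a prior count of 2. Direction between experiments used Fisher's exact test over genes called in both.

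Alternatives were RLE factors, library sizes alone, no count filter, a mean CPM of at least 1, DESeq2 1.42.0, limma-voom, replicate numbers as a block, protein-coding genes alone, the 2 groups alone, and each library left out in turn. Chosen after seeing the data were the protein-coding share of each library as a covariate, runs of other times, list counts and directions without 6-month replicate 3, lists under 3 of these settings and without that library with an estimated correlation, and the direction test without list members. Libraries of a group were checked for duplicates, and none was found. The steps were tested on simulated data drawn from the fitted means and spreads, with 200 changed genes. In the 15-day comparison 0%, 0% and 18.2% of changes of 1.5, 2 and 4-fold were recovered and 0 of 12 calls were false; in the knockdown 76.1%, 98.5% and 100% were recovered and 18 of 201 calls were false. Of random gene sets, 3 of 40 and 0 of 40 had p under 0.05. Figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Single values of 2 list members are not reported here.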

Results

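RNA was sequenced from LNCaP, a prostate cancer cell line that depends on androgen, in 21 libraries, 3 per group. The time course held 5 groups: cells grown with 2 nM of the androgen dihydrotestosterone (day 0), and cells kept in hormone-depleted medium for 15 days, 1 month, 3 months or 6 months. The knockdown held 2 groups, both 48 hours after transfection in hormone-depleted medium: cells given a pool of small interfering RNAs (siPOOL) against PROCA11, and cells given a scrambled siPOOL. PROCA11 has a count of its own in every library, but no position in the sources used here. Each value was a read count per gene, lists of genes were tested with camera, whose adjusted p follows the counts of each list, and CPM are these counts scaled to a common library size with TMM factors.

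Total counts were 232935373, 213179403 and 159985266 in the day-0 replicates 1, 2 and 3, 248212028, 212430176 and 191702233 at 15 days, 191709451, 181277661 and 178537426 at 1 month, 185623969, 237361841 and 203031008 at 3 months and 192919433, 210236023 and 263355443 at 6 months. They were 35066921, 49319049 and 33205653 with the PROCA11 siPOOL and 44034057, 53923280 and 39497084 with the scramble. Small and structural RNAs took 49.0% to 72.9% of the time course counts and 1.70% to 1.92% of the knockdown counts. Protein-coding genes took 5.34% (6-month replicate 3) to 31.6% (day-0 replicate 3) in the time course and 78.4% to 79.2% in the knockdown, so levels were not compared between the 2 experiments. A count of 0 allows up to 0.00838 to 0.0364 CPM in a time course library and 0.0557 to 0.0907 CPM in a knockdown library, for counting error only (3 counts over the TMM-scaled total). No log2 change is given where a group mean lay under the limits of its libraries.

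Libraries of one group correlated at r = 0.994 to 0.996 across genes in the knockdown and at r = 0.890 to 0.994 in the time course, where genes are not independent replicates. The spread between replicates (biological coefficient of variation) was 41.0% in the time course and 3.64% in the knockdown. In the time course, 6-month replicate 3 stood apart from its group: it correlated with 6-month replicates 1 and 2 at r = 0.890 and r = 0.890, and with the 3-month libraries at r = 0.960 to 0.973. The proliferation marker MKI67 was at 10.3, 13.7 and 0.0364 CPM in 6-month replicates 1, 2 and 3. On the first principal component, day-0 libraries lay at -136.7 to -113.4 and 3-month libraries at 82.8 to 140.2. 6-month replicates 1, 2 and 3 lay at -107.9, -103.5 and 125.6.

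**Figure D1:**
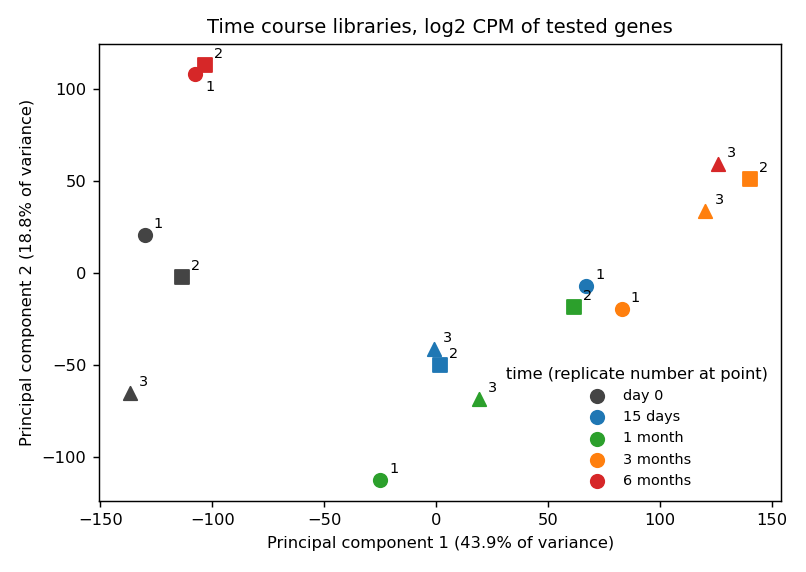
First against second principal component of log2 CPM in the 15 time course libraries (43.9% and 18.8% of the variance), 1 point per library, coloured by time without hormone. 6-month replicate 3 lies among the 3-month libraries, away from replicates 1 and 2.

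The comparison of 15 days with day 0 asked which genes change when androgen is withdrawn. KLK3 (prostate-specific antigen; ENSG00000142515.15, chromosome 19, 50854915 to 50860764, GRCh38) fell from 417 ± 164 to 11.5 ± 2.77 CPM (mean ± SD, n = 3), and the neighbouring kallikrein KLK2 from 100.5 ± 33.4 to 2.74 ± 0.425 CPM. AOC1, the diamine oxidase gene (ENSG00000002726.20, chromosome 7, 150824627 to 150861504), rose from 0.0512 ± 0.0350 to 12.5 ± 9.61 CPM, and IL1B, an inflammatory cytokine, from 0.0543 ± 0.0184 to 5.34 ± 2.42 CPM. The linker histone gene H1-5, used in DNA replication, fell from 73.7 ± 85.7 to 0.584 ± 0.188 CPM. On the log2 scale (± SE) the changes were -5.19 ± 0.68 for KLK3 (adjusted p = 0.00195), -5.20 ± 0.62 for KLK2 (0.00163), 8.03 ± 0.77 for AOC1 (0.000245), 6.66 ± 1.06 for IL1B (0.00454) and -6.98 ± 1.21 for H1-5 (0.00745).

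Of 29 tested androgen-induced targets, 11 were called lower, 0 higher and 18 neither (15 and 1 adjusted over the list alone). Adjusted p was 4.47e-10 (adjusted p = 0.0243 with an estimated correlation). Beside the kallikreins, the cold-sensing channel gene TRPM8 (-4.48 ± 0.68, adjusted p = 0.00359), the prostate transporter gene SLC45A3 (-2.34 ± 0.40, adjusted p = 0.00721) and the protease gene TMPRSS2 (-2.12 ± 0.37, adjusted p = 0.00745) fell. FKBP5, a co-chaperone of steroid receptors (-1.63 ± 0.66, adjusted p = 0.124), did not pass. Of 8 tested androgen-repressed genes, 4 were called higher, 0 lower and 4 neither (4 and 0 adjusted over the list alone). Adjusted p was 5.12e-05 (adjusted p = 0.0243 with an estimated correlation). The matricellular protein gene CCN3 (4.28 ± 0.69, adjusted p = 0.00506) and the kinase inhibitor gene CAMK2N1 (3.41 ± 0.62, adjusted p = 0.00910) rose. With an estimated correlation and without 6-month replicate 3, neither list passed (adjusted p = 0.0650 for both).

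Of 31 tested cell cycle genes, 9 were called lower, 0 higher and 22 neither (23 and 0 adjusted over the list alone). Adjusted p was 9.99e-10 (adjusted p = 0.274 with an estimated correlation). The histone gene H3C2 fell by 7.69 and the cyclin gene CCNB2 by 4.79 on the log2 scale (adjusted p = 0.0144 and 0.0164), and MKI67 went from 4.50 ± 2.23 to 0.283 ± 0.0110 CPM (adjusted p = 0.0316). These calls were lost for H3C2 without 3 libraries in turn (adjusted p = 0.0532 to 0.0842); for CCNB2 without 4 libraries in turn (adjusted p = 0.0545 to 0.0898); for MKI67 without 5 libraries in turn (adjusted p = 0.0685 to 0.136). Of 18 tested DNA repair genes, 2 were called lower, 0 higher and 16 neither (7 and 0 adjusted over the list alone). Adjusted p was 5.12e-05 (adjusted p = 0.336 with an estimated correlation). Of 26 ribosomal protein genes, 14 were called lower, 0 higher and 12 neither (19 and 0 adjusted over the list alone). Adjusted p was 2.53e-12 (adjusted p = 0.158 with an estimated correlation). Among 18 long non-coding RNAs of the prostate or nucleus, 5 were called lower, 0 higher and 13 neither (7 and 1 adjusted over the list alone). Adjusted p was 0.00217 (adjusted p = 0.134 with an estimated correlation).

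Of 17 tested neuroendocrine and neuronal markers, 5 were called higher, 0 lower and 12 neither (8 and 0 adjusted over the list alone). Adjusted p was 0.000118 (adjusted p = 0.152 with an estimated correlation). ENO2, a neuronal enolase, rose by 2.21 ± 0.65, adjusted p = 0.0462, a call lost without 6 libraries in turn (adjusted p = 0.0691 to 0.161). The synaptic vesicle gene SYP (1.49 ± 0.55, adjusted p = 0.0942) did not pass, and CHGA was not tested, with 2 reads in the time course and 1 in the knockdown. Among 17 nuclear receptors, 4 were called higher, 0 lower and 13 neither (6 and 0 adjusted over the list alone). Adjusted p was 0.00198 (adjusted p = 0.132 with an estimated correlation). NR4A2, an orphan receptor, rose by 2.64 ± 0.41, adjusted p = 0.00393. The estrogen receptor gene ESR1 had no read at day 0 and 0.197 ± 0.0376 CPM at 15 days. Among 22 interferon response genes, 4 were called higher, 0 lower and 18 neither (6 and 0 adjusted over the list alone). Adjusted p was 0.00449 (adjusted p = 0.132 with an estimated correlation). The smallest adjusted p was that of IFIT1 (2.03 ± 0.36, adjusted p = 0.00811). Among 13 NF-kB targets, 3 were called higher, 0 lower and 10 neither (4 and 0 adjusted over the list alone). Adjusted p was 0.00189 (adjusted p = 0.152 with an estimated correlation).

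Of 14 cell cycle inhibitors and senescence secretory genes, 2 were called higher, 0 lower and 12 neither (3 and 0 adjusted over the list alone). Adjusted p was 0.00261 (adjusted p = 0.152 with an estimated correlation). CDKN1A, the p21 inhibitor (-0.20 ± 0.39, adjusted p = 0.762), did not pass. Of 20 unfolded protein and amino acid stress genes, 1 was called lower, 0 higher and 19 neither (1 and 0 adjusted over the list alone). Adjusted p was 0.0206 (adjusted p = 0.164 with an estimated correlation), a call lost without day-0 replicate 3 (adjusted p = 0.115), and with library sizes alone (0.0501). Of 15 polymerase III and mitochondrial transcripts, 3 were called lower, 0 higher and 12 neither (8 and 0 adjusted over the list alone). Adjusted p was 0.000118 (adjusted p = 0.113 with an estimated correlation). PROCA11 rose from 59.2 ± 18.1 to 175 ± 16.9 CPM (1.56 ± 0.34, adjusted p = 0.0170), a call lost without 3 libraries in turn (adjusted p = 0.0571 to 0.0763). The lists that did not pass, with members called higher and lower and adjusted p, were the luminal markers (1 and 2 of 21, 0.759), basal and stem cell markers (0 and 1 of 9, 0.620), mesenchymal genes (1 and 3 of 16, 0.873), steroid enzymes (1 and 1 of 16, 0.174), cholesterol and fatty acid genes (0 and 0 of 23, 0.873), hypoxia and glycolysis genes (0 and 3 of 17, 0.174) and markers of immune, endothelial and stromal cells (0 and 0 of 11, 0.0743); under other settings the immune and stromal markers (7 of 12) and hypoxia genes (1) passed. Median, mean and test differed in sign for the luminal markers (0.35, -0.11 and up), the mesenchymal genes (0.35, -0.23 and down) and the cholesterol genes (-0.13, 0.06 and up).

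In all, 2667 of 29023 genes were called (1421 higher and 1246 lower), with 1367 at least 2-fold higher and 1184 at least 2-fold lower. The count was 242 without day-0 replicate 1, 527 without day-0 replicate 2, 231 without 15-day replicate 1, 999 without 15-day replicate 2, 539 without 15-day replicate 3 and 6482 without 6-month replicate 3. There were 192 higher and 39 lower without 15-day replicate 1, and 432 higher and 107 lower without replicate 3. Of 79 named calls, 21 held without each library in turn and 11 under all settings.

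The same question was asked at 1 month. AOC1 rose from 0.0512 ± 0.0350 to 11.2 ± 1.39 CPM (7.87 ± 0.77, adjusted p = 0.000237), IL1B from 0.0543 ± 0.0184 to 10.2 ± 2.27 CPM (7.59 ± 1.09, adjusted p = 0.00137) and VWC2L from 0.0443 ± 0.0271 to 5.72 ± 1.25 CPM (6.95 ± 0.44, adjusted p = 1.65e-06). The histone gene H3C2 fell from 93.4 ± 78.6 to 0.192 ± 0.124 CPM (-8.96 ± 1.65, adjusted p = 0.00495). KLK3 stood at 10.4 ± 9.21 CPM (-5.33 ± 0.69, adjusted p = 0.000758) and TMPRSS2 at 15.0 ± 6.00 CPM (-2.21 ± 0.37, adjusted p = 0.00325). Of 29 androgen-induced targets, 9 were called lower, 1 higher and 19 neither (10 and 1 adjusted over the list alone). Adjusted p was 3.10e-08 (adjusted p = 0.0430 with an estimated correlation). Of 8 androgen-repressed genes, 4 were called higher, 0 lower and 4 neither (5 and 0 adjusted over the list alone). Adjusted p was 4.38e-05 (adjusted p = 0.0430 with an estimated correlation). First in the list was MET, the hepatocyte growth factor receptor (4.18 ± 0.59, adjusted p = 0.00134). Neither list passed with an estimated correlation and without 6-month replicate 3 (adjusted p = 0.0776 for both).

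Of 31 cell cycle genes at 1 month, 15 were called lower, 0 higher and 16 neither (22 and 0 adjusted over the list alone). Adjusted p was 6.27e-11 (adjusted p = 0.233 with an estimated correlation). MKI67 was at 0.139 ± 0.0402 CPM (-5.00 ± 1.11, adjusted p = 0.0101). Of 18 DNA repair genes, 6 were called lower, 0 higher and 12 neither (9 and 0 adjusted over the list alone). Adjusted p was 3.07e-05 (adjusted p = 0.321 with an estimated correlation). The smallest adjusted p was that of BRIP1 (-4.70 ± 0.90, adjusted p = 0.00569). Of 26 ribosomal protein genes, 21 were called lower, 0 higher and 5 neither (24 and 0 adjusted over the list alone). Adjusted p was 9.86e-19 (adjusted p = 0.140 with an estimated correlation). Of 17 neuroendocrine markers, 8 were called higher, 0 lower and 9 neither (12 and 0 adjusted over the list alone). Adjusted p was 2.02e-05 (adjusted p = 0.140 with an estimated correlation). Called members included the receptor tyrosine kinase gene RET (3.85 ± 0.70, adjusted p = 0.00462) and the neuropeptide gene NTS (adjusted p = 0.00672). This list passed with an estimated correlation when 6-month replicate 3 was left out (adjusted p = 0.0354). Of 17 nuclear receptors, 5 were called higher, 0 lower and 12 neither (6 and 0 adjusted over the list alone). Adjusted p was 0.000126 (adjusted p = 0.0837 with an estimated correlation). Called members included the glucocorticoid receptor gene NR3C1 (3.20 ± 0.52, adjusted p = 0.00289) and the mineralocorticoid receptor gene NR3C2 (2.29 ± 0.38, adjusted p = 0.00319). Of 13 NF-kB targets, 4 were called higher, 0 lower and 9 neither (4 and 0 adjusted over the list alone). Adjusted p was 0.000279 (adjusted p = 0.140 with an estimated correlation). Of 14 cell cycle inhibitors and senescence genes, 4 were called higher, 0 lower and 10 neither (9 and 0 adjusted over the list alone). Adjusted p was 0.00235 (adjusted p = 0.157 with an estimated correlation). The smallest adjusted p was that of TIMP2 (2.26 ± 0.41, adjusted p = 0.00449).

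Of 15 polymerase III and mitochondrial transcripts at 1 month, 2 were called lower, 0 higher and 13 neither (2 and 0 adjusted over the list alone). Adjusted p was 0.00235 (adjusted p = 0.140 with an estimated correlation). Of 22 interferon genes, 4 were called higher, 0 lower and 18 neither (5 and 0 adjusted over the list alone). Adjusted p was 0.0149 (adjusted p = 0.140 with an estimated correlation), a call lost without 3 libraries in turn (adjusted p = 0.0524 to 0.0700), and with library sizes alone (adjusted p = 0.0515). Of 18 long non-coding RNAs, 3 were called lower, 2 higher and 13 neither (5 and 2 adjusted over the list alone). Adjusted p was 0.0250 (adjusted p = 0.200 with an estimated correlation), a call lost without day-0 replicate 3 (adjusted p = 0.109), and with library sizes alone (0.0515). Of 20 stress response genes, 1 was called lower, 0 higher and 19 neither (1 and 0 adjusted over the list alone). Adjusted p was 0.0184 (adjusted p = 0.164 with an estimated correlation), a call lost without day-0 replicate 3 (adjusted p = 0.112) and 1-month replicate 1 (0.0719), and with library sizes alone (0.0565). PROCA11 rose to 208 ± 21.1 CPM (1.82 ± 0.34, adjusted p = 0.00522), with all 3 libraries above all 3 of day 0. The other 7 lists had adjusted p from 0.0627 to 0.959, and under other settings the hypoxia genes (4 of 12), steroid enzymes (1) and immune and stromal markers (1) passed. Signs of median, mean and test differed for the luminal markers (0.18, -0.05 and up), the basal and stem cell markers (-0.03, -0.06 and up) and the cholesterol genes (0.12, 0.03 and down). In all, 4380 of 29023 genes were called (2368 higher and 2012 lower). The count was 1345 without day-0 replicate 1, 2032 without day-0 replicate 2, 2719 without 1-month replicate 1, 1412 without 1-month replicate 3 and 7349 without 6-month replicate 3.

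At 3 months SHH, a hedgehog ligand, was at 16.1 ± 8.63 CPM, with 2, 0 and 10 reads at day 0 (adjusted p = 0.00124), and IL1B (9.66 ± 1.17, adjusted p = 0.000250) and AOC1 (9.55 ± 0.81, adjusted p = 4.53e-05) rose. The largest falls were in H3C2 (-9.33 ± 1.68, adjusted p = 0.00157) and TOP2A, the DNA topoisomerase of dividing cells (12.9 ± 10.9 to 0.0296 ± 0.0225 CPM, adjusted p = 0.00183). KLK3 was at 12.8 ± 7.01 CPM (-5.03 ± 0.68, adjusted p = 0.000457). ENO2 rose to 23.8 ± 3.53 CPM (3.19 ± 0.67, adjusted p = 0.00320) and SYP to 2.32 ± 0.764 CPM (2.95 ± 0.57, adjusted p = 0.00211). FKBP5 fell by 2.19 on the log2 scale (adjusted p = 0.0189), a call lost without 3 libraries in turn (adjusted p = 0.0575 to 0.114).

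Of 17 tested neuroendocrine markers at 3 months, 13 were called higher, 0 lower and 4 neither (14 and 0 adjusted over the list alone). Adjusted p was 5.18e-05 (adjusted p = 0.135 with an estimated correlation). With 6-month replicate 3 left out it passed with an estimated correlation (adjusted p = 0.0481). Of 13 NF-kB targets, 10 were called higher, 0 lower and 3 neither (10 and 0 adjusted over the list alone). Adjusted p was 4.92e-05 (adjusted p = 0.0952 with an estimated correlation). Called members included the subunit gene RELB (3.06 ± 0.45, adjusted p = 0.000657). Of 14 cell cycle inhibitors and senescence genes, 8 were called higher, 0 lower and 6 neither (9 and 0 adjusted over the list alone). Adjusted p was 0.000120 (adjusted p = 0.0952 with an estimated correlation). Called members included the inhibitor gene CDKN2D (1.90 ± 0.31, adjusted p = 0.00107). Of 17 nuclear receptors, 9 were called higher, 1 lower and 7 neither (9 and 1 adjusted over the list alone). Adjusted p was 0.00199 (adjusted p = 0.0952 with an estimated correlation). Of 22 interferon genes, 9 were called higher, 0 lower and 13 neither (9 and 0 adjusted over the list alone). Adjusted p was 0.00748 (adjusted p = 0.106 with an estimated correlation), a call lost with protein-coding genes alone (adjusted p = 0.0805). Of 8 androgen-repressed genes, 4 were called higher, 0 lower and 4 neither (4 and 0 adjusted over the list alone). Adjusted p was 0.00748 (adjusted p = 0.0952 with an estimated correlation). Of 29 androgen-induced targets, 16 were called lower, 1 higher and 12 neither (16 and 1 adjusted over the list alone). Adjusted p was 5.18e-05 (adjusted p = 0.0952 with an estimated correlation).

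Of 31 cell cycle genes at 3 months, 22 were called lower, 0 higher and 9 neither (22 and 0 adjusted over the list alone). Adjusted p was 6.28e-06 (adjusted p = 0.442 with an estimated correlation). Of 18 DNA repair genes, 12 were called lower, 1 higher and 5 neither (15 and 1 adjusted over the list alone). Adjusted p was 3.10e-05 (adjusted p = 0.356 with an estimated correlation). Called members included the checkpoint kinase gene ATR (-2.15 ± 0.46, adjusted p = 0.00340). Of 26 ribosomal protein genes, 19 were called lower, 0 higher and 7 neither (22 and 0 adjusted over the list alone). Adjusted p was 1.16e-09 (adjusted p = 0.246 with an estimated correlation). Of 18 long non-coding RNAs, 8 were called lower, 2 higher and 8 neither (11 and 2 adjusted over the list alone). Adjusted p was 0.00105 (adjusted p = 0.0952 with an estimated correlation). Called members included NEAT1, the scaffold of paraspeckles (-3.49 ± 0.65, adjusted p = 0.00187). Of 15 polymerase III and mitochondrial transcripts, 9 were called lower, 0 higher and 6 neither (9 and 0 adjusted over the list alone). Adjusted p was 5.18e-05 (adjusted p = 0.0952 with an estimated correlation). PROCA11 was at 148 ± 39.1 CPM (1.32 ± 0.34, adjusted p = 0.00772). The other 8 lists had adjusted p from 0.186 to 0.678, and under other settings the immune and stromal markers (1 of 12) passed. Median, mean and test differed in sign for the basal and stem cell markers (0.18, -0.22 and up), the stress response genes (0.06, -0.11 and down) and the hypoxia genes (-0.15, 0.11 and down). In all, 11958 of 29023 genes were called (6488 higher and 5470 lower). The count was 7517 without 3-month replicate 3.

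**Figure D2:**
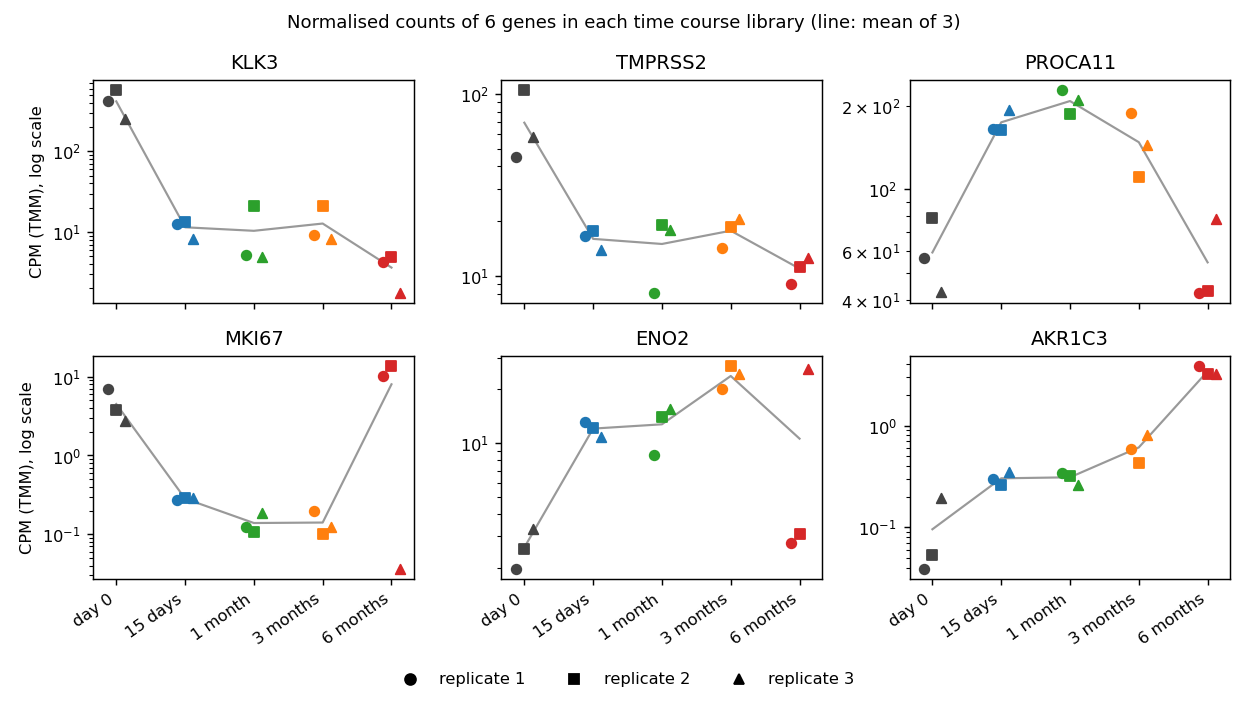
CPM on a log axis of KLK3, TMPRSS2, PROCA11, MKI67, ENO2 and AKR1C3 in each time course library (points) with group means, against time without hormone. KLK3 falls from 417 ± 164 CPM at day 0 to 3.63 ± 1.64 CPM at 6 months, and MKI67 at 6 months is at 10.3, 13.7 and 0.0364 CPM in replicates 1, 2 and 3.

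At 6 months, KLK3 was at its lowest, 3.63 ± 1.64 CPM against 417 ± 164 CPM at day 0 (-6.84 ± 0.74, adjusted p = 0.000142), and KLK2 fell to 1.71 ± 1.01 CPM (-5.86 ± 0.64, adjusted p = 0.000145). SEMA5A, a semaphorin of axon guidance (ENSG00000112902.12, chromosome 5, 9035026 to 9546075), had 1, 0 and 1 reads at day 0 and 18.4 ± 13.3 CPM at 6 months (adjusted p = 2.29e-05). NTS, which encodes neurotensin, had 1, 5 and 1 reads and 18.7 ± 9.61 CPM (adjusted p = 0.000155). SHH had 2, 0 and 10 reads and 12.8 ± 20.1 CPM (adjusted p = 0.00271). The SD of SHH was above its mean, so most of its 6-month level came from a single library. AOC1 rose to 44.4 ± 17.5 CPM (9.85 ± 0.82, adjusted p = 2.43e-05). REG4 (8.53 ± 1.76), LRRTM3 (8.19 ± 0.98), CTNNA3 (7.63 ± 1.16) and S100A14 (7.33 ± 1.15) followed on the log2 scale, with adjusted p of 0.00721, 0.000252, 0.00116 and 0.00143. Falls after the kallikreins were in BMPR1B, a receptor of bone morphogenetic proteins (-5.54 ± 0.86), SLC4A4, a bicarbonate transporter (-5.12 ± 0.65), and RLN1, a relaxin (-4.75 ± 0.52), with adjusted p of 0.00135, 0.000349 and 0.000145.

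Of 29 androgen-induced targets at 6 months, 11 were called lower, 0 higher and 18 neither (14 and 0 adjusted over the list alone). Adjusted p was 9.83e-11 (adjusted p = 0.0105 with an estimated correlation). Without 6-month replicate 3, the library that stood apart, the list gave 1 higher and 12 lower, adjusted p = 6.57e-09. TMPRSS2 changed by -2.67 ± 0.38, adjusted p = 0.000669, while FKBP5 (-0.22 ± 0.64, adjusted p = 0.845) did not pass. Of 8 androgen-repressed genes, 2 were called higher, 0 lower and 6 neither (6 and 0 adjusted over the list alone). Adjusted p was 0.000137 (adjusted p = 0.0105 with an estimated correlation). Without that library, 5 were higher and 0 lower (adjusted p = 4.96e-05). UGT2B17, an androgen-inactivating enzyme close in sequence to UGT2B15, had a log2 difference of 2.18 ± 0.87, adjusted p = 0.110 and did not pass. AKR1C3, which makes testosterone from androstenedione, rose from 0.0952 ± 0.0855 to 3.42 ± 0.374 CPM (5.10 ± 0.53, adjusted p = 0.000114), with near-identical AKR1C1 (4.23 ± 0.61) and AKR1C2 (4.14 ± 0.74) at adjusted p of 0.000801 and 0.00306. Of 16 steroid enzymes, 3 were called higher, 0 lower and 13 neither (4 and 0 adjusted over the list alone). Adjusted p was 0.00365 (adjusted p = 0.164 with an estimated correlation). Without that library, 8 were higher and 0 lower (adjusted p = 8.43e-07).

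Of 31 cell cycle genes at 6 months, 0 were called higher, 0 lower and 31 neither (0 and 0 adjusted over the list alone). Adjusted p was 0.101 (adjusted p = 0.783 with an estimated correlation). MKI67 had 10.3, 13.7 and 0.0364 CPM in replicates 1, 2 and 3 against 4.50 ± 2.23 CPM (mean ± SD) at day 0 (0.84 ± 0.93, adjusted p = 0.566). Without replicate 3 the list gave 13 higher and 0 lower, adjusted p = 1.19e-09 (adjusted p = 0.183 with an estimated correlation). Of 18 DNA repair genes, 0 were called lower, 0 higher and 18 neither (0 and 0 adjusted over the list alone). Adjusted p was 0.902 (adjusted p = 0.972 with an estimated correlation). Without replicate 3, 5 were higher and 0 lower (adjusted p = 0.00313; adjusted p = 0.358 with an estimated correlation). The mean of the cell cycle list relative to day 0 was -2.44 ± 0.15 (SD, n = 3) at 15 days, -2.75 ± 0.09 at 1 month, -2.91 ± 0.09 at 3 months and 0.18 ± 2.89 at 6 months.

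**Figure D3:**
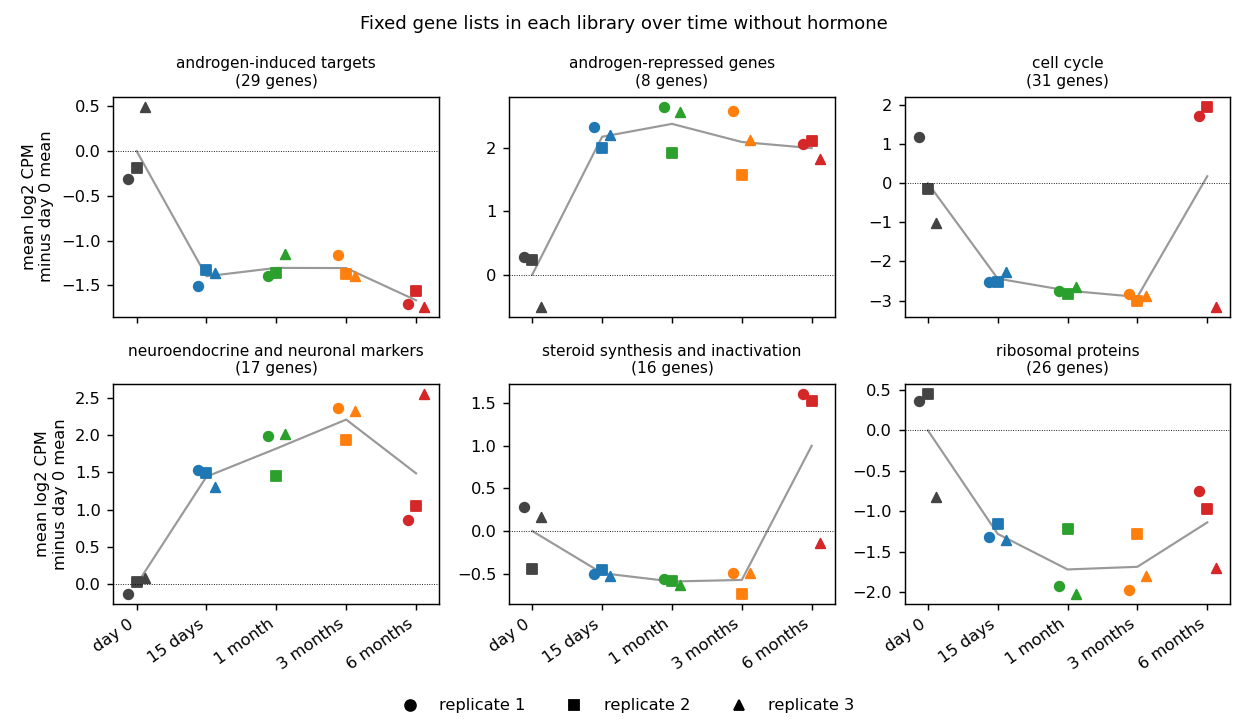
Mean log2 CPM of 6 gene lists relative to day 0 against time without hormone, 1 point per library, with marker shapes for the replicate numbers and a line through the group means. The cell cycle list stands at -2.91 ± 0.09 (SD, n = 3) at 3 months and at 0.18 ± 2.89 at 6 months, where replicate 3 lies apart.

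Among 17 nuclear receptors at 6 months, 8 were called higher, 0 lower and 9 neither (10 and 0 adjusted over the list alone). Adjusted p was 3.77e-09 (adjusted p = 0.00657 with an estimated correlation). Without 6-month replicate 3, 8 were higher and 0 lower (adjusted p = 6.57e-09). NR3C1 rose to 16.0 ± 5.88 CPM (4.41 ± 0.55, adjusted p = 0.000306), and ESR1 stood at 4.58 ± 4.36 CPM, with no read at day 0. Of 22 interferon genes, 9 were called higher, 0 lower and 13 neither (13 and 0 adjusted over the list alone). Adjusted p was 2.62e-08 (adjusted p = 0.00657 with an estimated correlation). First in the list was the antiviral synthetase gene OAS1 (3.34 ± 0.40, adjusted p = 0.000272). Without that library, 12 were higher and 0 lower (adjusted p = 7.01e-09). Of 13 NF-kB targets, 7 were called higher, 0 lower and 6 neither (11 and 0 adjusted over the list alone). Adjusted p was 1.78e-09 (adjusted p = 0.0142 with an estimated correlation). First in the list was RELB (3.31 ± 0.45, adjusted p = 0.000541). Without that library, 8 were higher and 0 lower (adjusted p = 1.02e-08). Of 14 cell cycle inhibitors and senescence genes, 6 were called higher, 0 lower and 8 neither (8 and 0 adjusted over the list alone). Adjusted p was 0.000106 (adjusted p = 0.0717 with an estimated correlation). Without that library, 7 were higher and 1 lower (adjusted p = 4.24e-05). Of 17 neuroendocrine markers, 3 were called higher, 0 lower and 14 neither (6 and 0 adjusted over the list alone). Adjusted p was 0.000853 (adjusted p = 0.191 with an estimated correlation). Without that library the list gave 3 higher and 1 lower, adjusted p = 0.198 (adjusted p = 0.338 with an estimated correlation), so its call rests on that library. NCAM1, a neural adhesion gene, rose by 4.96 ± 0.69, adjusted p = 0.000641, while ENO2 (2.02 ± 0.64, adjusted p = 0.0534) and SYP (1.72 ± 0.55, adjusted p = 0.0544) did not pass.

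Of 26 ribosomal protein genes at 6 months, 5 were called lower, 0 higher and 21 neither (19 and 0 adjusted over the list alone). Adjusted p was 3.56e-09 (adjusted p = 0.221 with an estimated correlation). Without 6-month replicate 3, 0 were higher and 5 lower (adjusted p = 1.82e-05). Of 18 long non-coding RNAs, 8 were called lower, 2 higher and 8 neither (11 and 3 adjusted over the list alone). Adjusted p was 0.00116 (adjusted p = 0.0863 with an estimated correlation). Without that library, 2 were higher and 6 lower (adjusted p = 0.00661). Of 15 polymerase III and mitochondrial transcripts, 3 were called lower, 0 higher and 12 neither (7 and 0 adjusted over the list alone). Adjusted p was 0.000247 (adjusted p = 0.0648 with an estimated correlation). Without that library, 0 were higher and 3 lower (adjusted p = 0.000408). Of 20 stress response genes, 2 were called lower, 0 higher and 18 neither (3 and 0 adjusted over the list alone). Adjusted p was 0.0158 (adjusted p = 0.164 with an estimated correlation), a call lost without day-0 replicate 3 (adjusted p = 0.0636), and with library sizes alone (0.0824). Of 11 tested markers of immune, endothelial and stromal cells, 5 were called higher, 0 lower and 6 neither (7 and 1 adjusted over the list alone). Adjusted p was 0.000337 (adjusted p = 0.0105 with an estimated correlation). Without 6-month replicate 3, 5 were higher and 1 lower (adjusted p = 0.000441). The macrophage marker CD68 was at 3.78 ± 2.70 CPM and the pericyte receptor PDGFRB at 0.628 ± 0.419 CPM (3.67 ± 0.60 and 4.55 ± 0.58, adjusted p = 0.00181 and 0.000381). PROCA11 was at 54.5 ± 20.6 CPM against 59.2 ± 18.1 CPM at day 0 (-0.12 ± 0.33, adjusted p = 0.834).

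With an estimated correlation as well, 7 of the 14 lists called without 6-month replicate 3 passed, the androgen-induced targets, senescence list, steroid enzymes, other nuclear receptors, interferon response genes, NF-kB targets and immune and stromal markers (adjusted p = 0.00973 to 0.0491), and 7 did not (adjusted p = 0.0838 to 0.358). The lists that did not pass at 6 months, beside the cell cycle and DNA repair lists, were (higher and lower, adjusted p) the luminal (3 and 1 of 21, 0.180), basal and stem cell (4 and 1 of 9, 0.205), mesenchymal (2 and 2 of 16, 0.631), cholesterol (2 and 0 of 23, 0.205) and hypoxia lists (1 and 1 of 17, 0.672); under other settings the cell cycle list (3 of 11) and DNA repair genes (1) passed. Signs of median, mean and test differed for the hypoxia genes (-0.22, 0.20 and down) and the DNA repair genes (0.55, 0.42 and down). In all, 3557 of 29023 genes were called (2336 higher and 1221 lower), with 2236 at least 2-fold higher and 1113 at least 2-fold lower. The count was 1909 without day-0 replicate 1 and 1747 without day-0 replicate 2, and 4648 without 6-month replicate 3.

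The next comparisons asked what changes after the first 15 days. Between 15 days and 1 month KLK3 (-0.15 ± 0.57, adjusted p = 1.00), MKI67 (-1.01 ± 0.99, adjusted p = 1.00) and PROCA11 (0.26 ± 0.33, adjusted p = 1.00) did not pass. The ribosomal protein list was lower at 1 month, with a median of -0.40 (adjusted p = 1.35e-08; adjusted p = 0.782 with an estimated correlation). So was the cell cycle list (adjusted p = 0.0214; adjusted p = 0.788 with an estimated correlation), a call lost without 15-day replicate 3 (adjusted p = 0.154) and 1-month replicate 2 (0.162). The nuclear receptor list was higher (adjusted p = 0.0250; adjusted p = 0.782 with an estimated correlation), a call lost without 4 libraries in turn (adjusted p = 0.0580 to 0.132). The other 17 lists had adjusted p from 0.125 to 0.999, and under other settings the NF-kB targets (7 of 12), neuroendocrine markers (6), polymerase III list (2), basal and stem cell markers (2), DNA repair genes (2), senescence list (1) and long non-coding RNA list (1) passed. Median, mean and test differed in sign for the luminal markers (0.07, 0.06 and down), the interferon response genes (-0.02, 0.06 and down), the stress response genes (-0.03, 0.03 and down) and the immune and stromal markers (0.17, 0.21 and down). No single gene was called by edgeR or limma-voom (0 of 29023, with 432 at an unadjusted p under 0.05), and DESeq2 called 1. In this and the next comparison no list had a member called over all genes.

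Between 1 month and 3 months, the cell cycle inhibitor and senescence list was higher (median 0.82, adjusted p = 0.00841; adjusted p = 0.457 with an estimated correlation), as was the NF-kB list (median 0.69, 3 members higher adjusted over the list alone, adjusted p = 0.00960; adjusted p = 0.457 with an estimated correlation). The long non-coding RNA list (4 lower adjusted over the list alone, adjusted p = 0.00841; adjusted p = 0.457 with an estimated correlation), the polymerase III and mitochondrial list (7 lower, adjusted p = 0.00592; adjusted p = 0.457 with an estimated correlation) and the DNA repair list (1 lower, adjusted p = 0.0344; adjusted p = 0.774 with an estimated correlation) were lower. The cholesterol and fatty acid list was higher (4 adjusted over the list alone, adjusted p = 0.0462; adjusted p = 0.549 with an estimated correlation), and with replicate numbers as a block it did not pass (adjusted p = 0.0638). With protein-coding genes alone the senescence, NF-kB and cholesterol lists did not pass (adjusted p = 0.0819, 0.0889 and 0.595), with library sizes alone the polymerase III, DNA repair and cholesterol lists did not (0.0516, 0.0516 and 0.0800), and with the protein-coding share as covariate the DNA repair list did not (0.129). Without 1-month replicate 2, none of these 6 lists passed (adjusted p = 0.0644 for 5 and 0.0723 for the cholesterol list). Other libraries whose loss ended a call were for the NF-kB list 3-month replicate 3 (adjusted p = 0.117), for the DNA repair list 3-month replicate 2 (0.0944) and for the cholesterol list 1-month replicate 1 (0.0860), 3-month replicate 1 (0.136), 3-month replicate 3 (0.0668) and 6-month replicate 3 (0.0788). CDKN1A (1.36 ± 0.40, adjusted p = 0.139) and SYP (1.26 ± 0.53, adjusted p = 0.202) did not pass. No single gene was called by edgeR or limma-voom (0 of 29023, with 6344 at an unadjusted p under 0.05; 0 with replicates as a block), and DESeq2 called 1444. Without 1-month replicate 2 edgeR called 60, and without 6-month replicate 3, 1907. The other 14 lists had adjusted p from 0.0720 to 0.927, and under other settings the luminal markers (3 of 12), stress response genes (3), interferon response genes (1) and neuroendocrine markers (1) passed. Signs of median, mean and test differed for the androgen-induced targets (0.03, -0.05 and up), the basal and stem cell markers (0.19, -0.15 and up), the steroid enzymes (-0.15, -0.07 and up) and the other nuclear receptors (-0.21, 0.07 and up).

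Between 3 and 6 months, TOP2A went from 0.0296 ± 0.0225 to 33.3 ± 29.3 CPM and H3C2 from 0.147 ± 0.0546 to 93.5 ± 80.6 CPM; TOP2A was at 44.1, 55.6 and 0.0728 CPM in 6-month replicates 1, 2 and 3. On the log2 scale the rises were 9.95 ± 1.68, adjusted p = 0.0212 for TOP2A and 9.33 ± 1.68, adjusted p = 0.0212 for H3C2. SOHLH2, a germline transcription factor, had 3, 1 and 3 reads at 3 months and 7.32 ± 6.34 CPM at 6 months (adjusted p = 0.0176). The immune checkpoint ligand gene CD274 (-3.78 ± 0.74, adjusted p = 0.0223), the sodium pump gene ATP1B1 (-2.98 ± 0.67, adjusted p = 0.0309) and PROCA11 (-1.44 ± 0.34, adjusted p = 0.0347) fell. Of 31 cell cycle genes, 20 were called higher, 0 lower and 11 neither (26 and 0 adjusted over the list alone). Adjusted p was 4.89e-17 (adjusted p = 0.346 with an estimated correlation). Of 18 DNA repair genes, 8 were called higher, 0 lower and 10 neither (14 and 0 adjusted over the list alone). Adjusted p was 1.21e-09 (adjusted p = 0.346 with an estimated correlation). Of 16 steroid enzymes, 6 were called higher, 0 lower and 10 neither (9 and 0 adjusted over the list alone). Adjusted p was 6.95e-06 (adjusted p = 0.280 with an estimated correlation). Without 6-month replicate 3 these lists gave 29 higher and 0 lower, adjusted p = 1.66e-27 (adjusted p = 0.114 with an estimated correlation), then 16 higher and 0 lower, adjusted p = 5.05e-14 (adjusted p = 0.114 with an estimated correlation), and 11 higher and 1 lower, adjusted p = 1.63e-06 (adjusted p = 0.0410 with an estimated correlation). The ribosomal protein list (adjusted p = 0.00302; adjusted p = 0.604 with an estimated correlation) and the polymerase III and mitochondrial list (adjusted p = 0.0432; adjusted p = 0.346 with an estimated correlation) were higher with 0 members called, calls lost without 3-month replicate 1 (adjusted p = 0.0991) for the first and without 3 libraries in turn (0.0508 to 0.291), and with library sizes alone (adjusted p = 0.191) for the second.

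In the comparison of 6 months with 3 months, 968 of 29023 genes were called (726 higher and 242 lower). The count was 0 without 3-month replicate 1, 0 without 3-month replicate 2, 13 without 3-month replicate 3, 0 without 6-month replicate 1, 0 without 6-month replicate 2 and 10969 without 6-month replicate 3, and every gene named here lost its call without each of the first 5 of these; for TOP2A the adjusted p reached 0.0980, for CD274 0.0980 and for PROCA11 0.196. Of the 10969 called without 6-month replicate 3, 4983 were higher and 5986 lower. The other 15 lists had adjusted p from 0.0563 to 0.897, and under other settings the interferon response genes (8 of 11), neuroendocrine markers (7), other nuclear receptors (3), stress response genes (2) and mesenchymal genes (1) passed. Median, mean and test differed in sign for the androgen-repressed genes (0.22, 0.33 and down), the luminal markers (-0.18, 0.15 and down) and the mesenchymal genes (-0.16, 0.14 and down). The neuroendocrine list was lower without 6-month replicate 3 (1 higher and 10 lower, adjusted p = 0.00163; adjusted p = 0.0747 with an estimated correlation), as were the mesenchymal genes (3 higher and 8 lower, adjusted p = 0.0356; adjusted p = 0.269 with an estimated correlation).

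Between 15 days and 6 months, S100A14, a calcium-binding protein gene, rose from 1, 0 and 3 reads to 5.91 ± 4.95 CPM (adjusted p = 0.00417), SOHLH2 from 0.0167 ± 0.0104 to 7.32 ± 6.34 CPM (8.73 ± 1.34, adjusted p = 0.00541) and the cytokine gene IL32 from 0.170 ± 0.134 to 14.3 ± 8.67 CPM (6.38 ± 0.89, adjusted p = 0.00417). CD274 fell from 20.1 ± 5.31 to 0.794 ± 0.920 CPM (-4.72 ± 0.77, adjusted p = 0.00625) and SLC4A4 from 24.6 ± 11.1 to 1.12 ± 1.07 CPM (-4.49 ± 0.63, adjusted p = 0.00417). The largest fall was in the collagen gene COL12A1 (-4.90 ± 0.99, adjusted p = 0.0145), a call lost without 15-day replicate 2 (adjusted p = 0.0582). AKR1C1 (4.86 ± 0.63), AKR1C3 (3.50 ± 0.48) and AKR1C2 (5.22 ± 0.78) rose, with adjusted p of 0.00417, 0.00417 and 0.00528, and ESR1 by 4.53 ± 0.64, adjusted p = 0.00531. PROCA11 fell from 175 ± 16.9 to 54.5 ± 20.6 CPM (-1.68 ± 0.34, adjusted p = 0.0143), a call lost without 5 libraries in turn (adjusted p = 0.0508 to 0.0837). KLK3 (-1.66 ± 0.59, adjusted p = 0.145) did not pass.

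Of 31 cell cycle genes between 15 days and 6 months, 18 were called higher, 0 lower and 13 neither (29 and 0 adjusted over the list alone). Adjusted p was 5.08e-18 (adjusted p = 0.206 with an estimated correlation). Without 6-month replicate 3, 30 were higher and 0 lower (adjusted p = 3.87e-34). Of 16 steroid enzymes, 5 were called higher, 0 lower and 11 neither (7 and 0 adjusted over the list alone). Adjusted p was 1.61e-07 (adjusted p = 0.0621 with an estimated correlation). Without that library, 11 were higher and 0 lower (adjusted p = 4.56e-09). Of 17 nuclear receptors, 5 were called higher, 0 lower and 12 neither (5 and 0 adjusted over the list alone). Adjusted p was 1.81e-05 (adjusted p = 0.0621 with an estimated correlation). Without that library, 8 were higher and 1 lower (adjusted p = 0.00427). Of 18 DNA repair genes, 5 were called higher, 0 lower and 13 neither (12 and 0 adjusted over the list alone). Adjusted p was 1.81e-05 (adjusted p = 0.537 with an estimated correlation). Without that library, 13 were higher and 0 lower (adjusted p = 5.06e-12). Of 22 interferon genes, 5 were called higher, 0 lower and 17 neither (7 and 1 adjusted over the list alone). Adjusted p was 0.000293 (adjusted p = 0.0621 with an estimated correlation). Without that library, 11 were higher and 3 lower (adjusted p = 0.00200). With an estimated correlation as well, 1 of the 5 lists called without 6-month replicate 3 passed, the steroid enzymes (adjusted p = 0.0191), and 4 did not (adjusted p = 0.108 to 0.283). Of 13 NF-kB targets, 1 was called higher, 0 lower and 12 neither (5 and 0 adjusted over the list alone). Adjusted p was 1.98e-05 (adjusted p = 0.104 with an estimated correlation), a call lost without 6-month replicate 3 (adjusted p = 0.0777). Of 11 immune, endothelial and stromal markers, 2 were called higher, 0 lower and 9 neither (2 and 0 adjusted over the list alone). Adjusted p was 0.0107 (adjusted p = 0.0621 with an estimated correlation), a call lost without 3 libraries in turn (adjusted p = 0.102 to 0.184), and with protein-coding genes alone (adjusted p = 0.0713). Of 9 basal and stem cell markers, 2 were called higher, 0 lower and 7 neither (4 and 0 adjusted over the list alone). Adjusted p was 0.0339 (adjusted p = 0.118 with an estimated correlation), a call lost without 6-month replicate 2 (adjusted p = 0.242) and 6-month replicate 3 (0.172), and with library sizes alone (0.0911).

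In the comparison of 6 months with 15 days, 1176 of 29023 genes were called (830 higher and 346 lower). The count was 279 without 15-day replicate 1, 245 without 15-day replicate 2, 329 without 15-day replicate 3, 375 without 6-month replicate 1, 306 without 6-month replicate 2 and 6239 without 6-month replicate 3. Of the 6239 called without 6-month replicate 3, 3088 were higher and 3151 lower. The other 12 lists had adjusted p from 0.129 to 0.991, and under other settings the senescence list (2 of 11) passed. Signs of median, mean and test differed for the androgen-repressed genes (0.75, 0.27 and down), the neuroendocrine markers (-0.13, 0.34 and down), the long non-coding RNA list (0.07, 0.15 and down) and the polymerase III list (0.15, 0.18 and down). One test over all 5 times called 8168 of 29023 genes, and 5102 without day-0 replicate 1, 5084 without day-0 replicate 2, 5315 without 3-month replicate 3 and 14859 without 6-month replicate 3.

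The knockdown asked what follows a lower level of PROCA11. The siPOOL lowered PROCA11 in every library, to 106, 109 and 105 CPM against 148, 145 and 154 CPM with the scramble (-0.48 ± 0.04, adjusted p = 7.01e-08, n = 3 per group). KLK3 fell from 301 ± 42.1 to 119 ± 26.2 CPM (-1.34 ± 0.11, adjusted p = 1.95e-07), KLK2 from 29.5 ± 4.52 to 10.00 ± 2.65 CPM (-1.59 ± 0.13, adjusted p = 1.61e-07) and the filament gene VIM from 5.48 ± 0.223 to 1.93 ± 0.332 CPM (-1.53 ± 0.12, adjusted p = 1.25e-07). AGR2, an endoplasmic reticulum disulfide isomerase (-1.15 ± 0.06), the interferon-inducible GTPase gene GBP2 (-0.95 ± 0.08), the pseudogene FAR2P3 (-0.94 ± 0.10) and NPC1, a lysosomal cholesterol transporter (-0.91 ± 0.04), were next, with adjusted p of 1.31e-09, 4.75e-07, 3.57e-06 and 2.57e-10. BVES, a membrane adhesion gene (ENSG00000112276.14, chromosome 6, 105096822 to 105137174), rose from 4.28 ± 0.0849 to 17.1 ± 1.07 CPM (1.99 ± 0.07, adjusted p = 1.34e-11).

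The next largest rises among genes at 5 CPM or more included neighbours on chromosome 3. The zinc finger gene MYNN (ENSG00000085274.15, 169772831 to 169789716) rose from 69.9 ± 0.303 to 202 ± 14.4 CPM (1.53 ± 0.04, adjusted p = 8.48e-13) and the actin-related gene ACTRT3 (ENSG00000184378.3, 169766921 to 169769895) from 6.05 ± 0.693 to 17.4 ± 0.948 CPM (1.52 ± 0.08, adjusted p = 1.17e-09). MECOM, a transcription factor of blood stem cells (ENSG00000085276.19, 169083499 to 169663618), rose from 4.83 ± 0.350 to 10.7 ± 0.805 CPM (1.15 ± 0.08, adjusted p = 5.87e-08). TERC, the telomerase RNA, which holds the model Telomerase-vert, rose by 1.57 ± 0.14, adjusted p = 4.88e-07. Chosen after these values were seen, the stretch from MECOM to LRRC31 held 11 tested models, of which 9 rose, by 1.03 to 1.86 (log2). The pseudogenes RPL22P1 (0.06 ± 0.04, adjusted p = 0.357) and SDHDP3 (-0.28 ± 0.25, adjusted p = 0.514) within it, and SEC62 (0.10 ± 0.04, adjusted p = 0.0789) and GPR160 (0.07 ± 0.05, adjusted p = 0.346) beyond it, did not pass. On its other side SERPINI1 (0.71 ± 0.06, adjusted p = 3.53e-07) and GOLIM4 (0.23 ± 0.05, adjusted p = 0.00267) rose. Elsewhere, the carbonic anhydrase gene CA13 (1.46 ± 0.08, adjusted p = 2.02e-09) and the ubiquitin ligase gene MID1 (1.26 ± 0.07, adjusted p = 2.02e-09) rose.

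**Figure D4:**
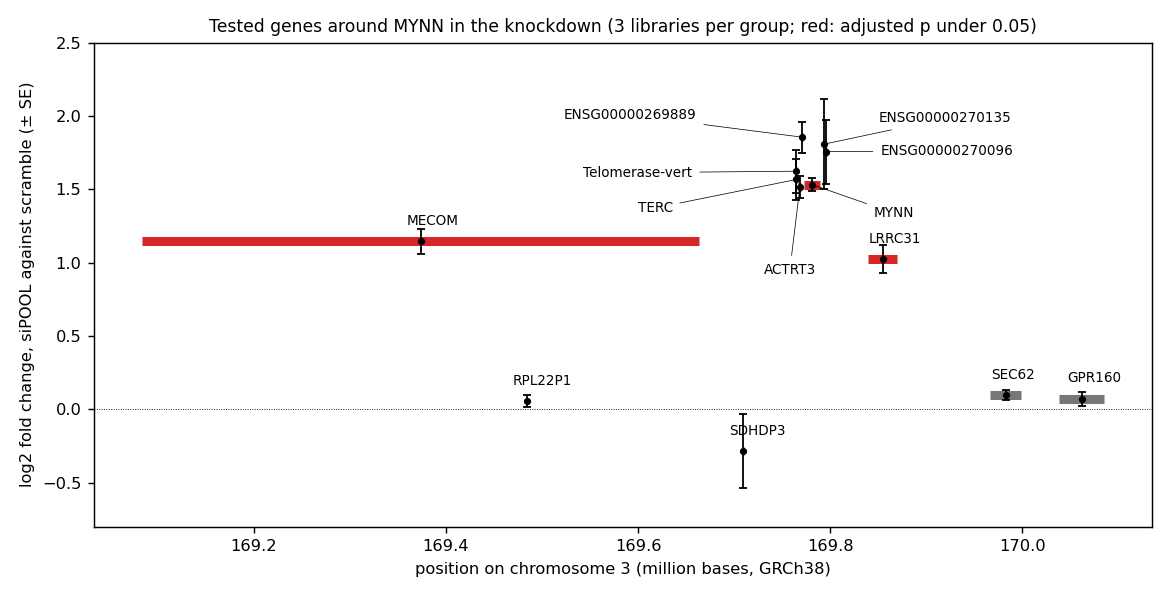
Log2 fold change (± SE) of the tested genes around MYNN with the PROCA11 siPOOL against the scramble (3 libraries per group), by position on chromosome 3 in Mb (GRCh38), with bars for gene bodies, red where called. MECOM to LRRC31 rose by 1.03 to 1.86, except RPL22P1 and SDHDP3, and SEC62 and GPR160 did not pass.

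Of 28 tested androgen-induced targets, 12 were called lower, 1 higher and 15 neither (14 and 1 adjusted over the list alone). Adjusted p was 5.97e-11 (adjusted p = 0.199 with an estimated correlation). The kallikrein gene KLK4 (-0.74 ± 0.05, adjusted p = 6.31e-08), TMPRSS2 (-0.56 ± 0.06, adjusted p = 5.46e-06) and the efflux transporter gene ABCC4 (-0.41 ± 0.04, adjusted p = 3.16e-06) fell, and FKBP5 (-0.12 ± 0.05, adjusted p = 0.130) did not pass. Of 8 androgen-repressed genes, 4 were called higher, 1 lower and 3 neither (4 and 1 adjusted over the list alone). Adjusted p was 0.00380 (adjusted p = 0.334 with an estimated correlation). CAMK2N1 (0.40 ± 0.03, adjusted p = 1.93e-07), OPRK1 (0.55 ± 0.06, adjusted p = 8.79e-06) and CCN3 (1.03 ± 0.20, adjusted p = 0.00147) rose. Of 11 tested neuroendocrine markers, 3 were called higher, 0 lower and 8 neither (4 and 0 adjusted over the list alone). Adjusted p was 0.000416 (adjusted p = 0.158 with an estimated correlation). Among them DDC, which makes dopamine and serotonin (0.42 ± 0.03), and TUBB3, a neuronal tubulin (0.52 ± 0.05), rose, with adjusted p of 8.47e-08 and 6.13e-07, while ENO2 (-0.02 ± 0.06, adjusted p = 0.885) and SYP (0.19 ± 0.14, adjusted p = 0.416) did not pass.

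Of 31 cell cycle genes, 23 were called lower, 0 higher and 8 neither (28 and 0 adjusted over the list alone). Adjusted p was 5.97e-11 (adjusted p = 0.418 with an estimated correlation). CCNE2, a cyclin of the start of DNA replication, fell by 0.40 on the log2 scale and TOP2A by 0.21 (adjusted p = 3.20e-05 and 0.00394). MKI67 changed by -0.14 ± 0.05, adjusted p = 0.0487, a call lost without 4 libraries in turn (adjusted p = 0.0756 to 0.231). CDKN1A (0.00 ± 0.04, adjusted p = 0.965) did not pass. Of 11 tested mesenchymal genes, 5 were called lower, 0 higher and 6 neither (6 and 0 adjusted over the list alone). Adjusted p was 2.27e-07 (adjusted p = 0.158 with an estimated correlation). Fibronectin (-0.62 ± 0.03 for FN1) and VIM fell. Of 20 stress response genes, 12 were called lower, 0 higher and 8 neither (12 and 0 adjusted over the list alone). Adjusted p was 3.72e-07 (adjusted p = 0.334 with an estimated correlation). Called members included XBP1, a factor of the unfolded protein response (-0.47 ± 0.04, adjusted p = 1.09e-06), and the serine synthesis gene PHGDH (-0.26 ± 0.03, adjusted p = 4.89e-05). Of 17 hypoxia and glycolysis genes, 7 were called lower, 0 higher and 10 neither (9 and 0 adjusted over the list alone). Adjusted p was 5.58e-06 (adjusted p = 0.334 with an estimated correlation). First in the list was the oxygen sensor gene EGLN3 (-0.82 ± 0.05, adjusted p = 8.58e-09).

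Of 18 DNA repair genes in the knockdown, 4 were called lower, 0 higher and 14 neither (4 and 0 adjusted over the list alone). Adjusted p was 0.0226 (adjusted p = 0.557 with an estimated correlation), a call lost without siPOOL replicate 3 (adjusted p = 0.145) and scramble replicate 1 (0.0694), and with protein-coding genes alone (0.0605). Of 15 steroid enzymes, 4 were called lower, 1 higher and 10 neither (4 and 1 adjusted over the list alone). Adjusted p was 0.0488 (adjusted p = 0.432 with an estimated correlation), a call lost without 4 libraries in turn (adjusted p = 0.0822 to 0.133), and with replicate numbers as a block (adjusted p = 0.0608) and with protein-coding genes alone (adjusted p = 0.0888). The other 11 lists had adjusted p from 0.119 to 0.743, and under other settings the ribosomal proteins (1 of 11) passed. Median, mean and test differed in sign for the senescence list (0.04, 0.01 and down), the long non-coding RNA list (0.01, -0.02 and down) and the immune and stromal markers (0.18, -0.17 and up). Among long non-coding RNAs, PCAT1, a prostate cancer transcript, fell by 0.62 ± 0.07, adjusted p = 1.42e-05. In all, 3699 of 22465 genes were called (1898 higher and 1801 lower), with 92 at least 2-fold higher and 55 at least 2-fold lower. The count was 2348 without scramble replicate 1 and 2286 without scramble replicate 2.

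The last comparison asked whether 4 sets of genes called at least 2-fold higher or lower against day 0 move in the knockdown. Of 1043 tested genes that had risen at 15 days, 222 were higher and 62 lower with the siPOOL (median 0.08, p = 1.04e-05 by camera; p = 0.155 with an estimated correlation). Of 1074 that had fallen at 15 days, 35 were higher and 182 lower with the siPOOL (median -0.06, p = 2.42e-06 by camera; p = 0.368 with an estimated correlation). Of 1649 that had risen at 6 months, 283 were higher and 131 lower with the siPOOL (median 0.05, p = 0.00410 by camera; p = 0.268 with an estimated correlation). Of 838 that had fallen at 6 months, 49 were higher and 99 lower with the siPOOL (median -0.03, p = 0.00473 by camera; p = 0.257 with an estimated correlation). Among 527 genes called both at 15 days and in the knockdown, 80.3% moved in the same direction: 232 rose in both and 191 fell in both, against 67 and 37 that went opposite ways (odds ratio 17.7, 95% interval 11.2 to 28.7, p = 3.71e-47 by Fisher's exact test over genes, which are not independent). At 6 months it was 69.2% of 603 genes (odds ratio 5.01, 3.34 to 7.58, p = 4.28e-17, same exact test). These shares, leaving out 6-month replicate 3, were 78.4% of 1123 genes and 56.6% of 701 genes (p = 2.92e-84 and p = 0.000650, same exact test).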

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

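The test of a 3-month library under a 6-month label was chosen only after the result was seen. Changes from day 0 differed between 6 months and 15 days, by the test of that difference, for 1176 genes. Lists differed too: the cell cycle (adjusted p = 5.08e-18), steroid enzymes (1.61e-07), other nuclear receptors (1.81e-05), DNA repair genes (1.81e-05), NF-kB targets (1.98e-05), interferon response genes (0.000293), immune, endothelial and stromal markers (0.0107) and basal and stem cell markers (0.0339). With an estimated correlation none of the 8 lists passed; the lowest adjusted p was 0.0621.

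In these comparisons 6-month replicate 3 stood apart: r was 0.890 and 0.890 with replicates 1 and 2, and 0.960 to 0.973 with 3-month libraries. Its low protein-coding share stays open: within-group slopes predicted a median 28.3% of the difference (at most 32.1% without one time). The 4247 genes were picked as 4-fold apart, and its share lay below those fitted. A 3-month library under a 6-month label cannot be told apart from a 6-month culture like those of 3 months: on a scale from 0 (3-month libraries) to 1 (6-month replicates 1 and 2), it lay at 0.0814, 0.0407 and 0.0504 (lowest 0.0407), and held-out 3-month libraries at 0.122, -0.0163 and 0.0216. On the side of replicates 1 and 2, 80, 72 and 110 genes lay 4-fold beyond the 3-month pairs in it, and 63, 25 and 21 in the held-out libraries. Of 20 lists, it lay beyond these pairs on that side in 9, 11 and 8, and the held-out libraries in 11, 7 and 5; on the other side it did in 5, 5 and 8, and they in 3, 7 and 7. Some lists go with its label: the androgen-induced mean was -1.74 in it, -1.71 and -1.56 in replicates 1 and 2, and -1.39 to -1.16 at 3 months, and the interferon mean was 1.22, 1.24 and 1.38, and 0.68 to 0.96 (log2, against day 0). Others do not: the cell cycle mean was -3.15, 1.73 and 1.95, and -3.01 to -2.82. A difference between cultures, such as dividing cells in replicates 1 and 2 alone, was not tested and stays open.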

How the results depend on the processing

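The protein-coding share as a covariate and the runs of other times without 6-month replicate 3 were chosen only after the results were seen. Times stand for comparisons with day 0 unless a second time is named, and causes were not tested unless given. The counts reported were 2667 (15 days), 4380 (1 month), 11958 (3 months), 3557 (6 months), 0 (1 month vs 15 days), 0 (3 months vs 1 month), 968 (6 vs 3 months), 1176 (6 months vs 15 days), 8168 (all 5 times) and 3699 (the siPOOL). Library sizes alone gave 83 (15 days), 790 (1 month), 2300 (3 months), 516 (6 months), 89 (6 vs 3 months), 236 (6 months vs 15 days) and 1492 (all 5 times) genes. DESeq2 gave 4926 (15 days), 5768 (6 months), 1 (1 month vs 15 days), 1444 (3 months vs 1 month), 3253 (6 vs 3 months), 2419 (6 months vs 15 days) and 12890 (all 5 times). Protein-coding genes alone, a smaller set, gave 1559 (15 days), 2335 (1 month), 7502 (3 months), 2308 (6 months) and 4998 (all 5 times). The covariate gave 6380 (15 days), 8808 (1 month), 6965 (6 months), 37 (3 months vs 1 month), 6325 (6 vs 3 months), 3176 (6 months vs 15 days) and 14836 (all 5 times). The 2 groups alone, with fewer libraries, gave 4576 (15 days), 386 (6 months), 2 (3 months vs 1 month), 0 (6 vs 3 months) and 0 (6 months vs 15 days). A mean CPM of at least 1, which tests fewer genes, gave 2758 (1 month), 7459 (3 months), 1834 (6 months), 218 (6 vs 3 months), 308 (6 months vs 15 days) and 4749 (all 5 times), and no count filter 290 (3 months vs 1 month), 1989 (6 vs 3 months) and 1773 (6 months vs 15 days). For 6 vs 3 months, limma-voom gave 2539 and replicate numbers as a block 575; libraries with the same replicate number deviated together only between 1 month and 3 months (correlations 0.247 to 0.598).

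Of calls, 53.3% (15 days), 54.1% (1 month), 54.3% (3 months), 65.7% (6 months), 75.0% (6 vs 3 months) and 70.6% (6 months vs 15 days) were higher. At the first 3 times library sizes alone gave 89.2%, 89.1% and 68.2%, RLE factors 44.7%, 45.0% and 47.7%, DESeq2 45.4%, 46.9% and 46.7%, the 2 groups alone 47.9%, 46.4% and 53.8% and protein-coding genes alone 51.9%, 49.7% and 49.4%. In later ones limma-voom gave 28.1% (6 vs 3 months) and 49.0% (6 months vs 15 days), the covariate 51.6% (6 months), 42.4% (6 vs 3 months) and 47.4% (6 months vs 15 days), and the 2 groups alone 78.8% (6 months). With one library left out the share ranged over 46.1% to 83.1% (15 days), 50.4% to 63.5% (1 month), 51.3% to 58.3% (3 months), 59.6% to 79.7% (6 months), 45.4% to 92.3% (6 vs 3 months), 49.5% to 79.7% (6 months vs 15 days) and 50.3% to 53.8% (the siPOOL), and counts ranged over 231 to 6482 (15 days), 1345 to 7349 (1 month), 7517 to 14553 (3 months), 1747 to 4648 (6 months), 0 to 0 (1 month vs 15 days), 0 to 1907 (3 months vs 1 month), 0 to 10969 (6 vs 3 months), 245 to 6239 (6 months vs 15 days), 5084 to 14859 (all 5 times) and 2286 to 4770 (the siPOOL). Deprivation sets in the knockdown had p = 0.155, 0.368, 0.268 and 0.257 with an estimated correlation, for genes risen and fallen at 15 days, then risen and fallen at 6 months; sets of the 200 smallest p had 0.101, 0.370, 0.0442 and 0.0808, so that risen at 6 months passed. With one knockdown library left out, the deprivation sets at the preset correlation had p of 1.25e-06 to 0.000221, 6.17e-12 to 0.000467, 0.00109 to 0.0353 and 0.000221 to 0.0329. Shares moving in the same direction then ranged over 79.5% to 85.8% (15 days) and 66.1% to 73.6% (6 months); without 6-month replicate 3 they were 78.4% and 56.6%. No named call reversed, and no list call under the settings run for lists: an estimated correlation, RLE factors, library sizes, the block, protein-coding genes, the covariate and left-out libraries. Lists not called turned 80 times, and 1 was then called, the DNA repair list at 6 months, up without 6-month replicate 3 (adjusted p = 0.00313; adjusted p = 0.358 with an estimated correlation). List calls that ended, beside left-out libraries, were 10 with library sizes alone (adjusted p = 0.0501 to 0.191), 7 with protein-coding genes alone (0.0605 to 0.595), 2 with the block (0.0608 to 0.0638) and 1 with the covariate (0.129). Calls gained were 5 with library sizes alone (adjusted p = 0.00197 to 0.0288), 8 with protein-coding genes alone (0.000171 to 0.0486), 2 with the block (0.0252 to 0.0427), 8 with the covariate (0.00136 to 0.0373) and 2 with RLE factors (0.0405 to 0.0491). Named calls kept under all settings were 11 of 79 (15 days), 24 of 82 (1 month), 51 of 91 (3 months), 22 of 79 (6 months), 0 of 36 (6 vs 3 months), 0 of 58 (6 months vs 15 days) and 72 of 88 (the siPOOL). With an estimated correlation, 2 of 13 (15 days), 2 of 13 (1 month), 0 of 12 (3 months), 6 of 13 (6 months), 0 of 8 (6 months vs 15 days) and 0 of 9 (the siPOOL) lists kept their call; without 6-month replicate 3 these were 0 of 14 (15 days), 1 of 12 (1 month), 1 of 12 (3 months) and 1 of 6 (6 vs 3 months).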

Other observations

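Both tests of the chromosome 3 stretch, and the count of list members, were chosen only after the results were seen. Around MYNN, 9 of 11 models rose with the siPOOL, counting Telomerase-vert inside TERC. For 5 of them, from ACTRT3 through MYNN to ENSG00000270096, chance is argued against: their mean log2 change was 1.69, and no window of 5 neighbours reached it in 10000 random gene orders (permutation p = 0.0001, the lowest they can give). Reads shared by overlap are argued against only in 5 genes that overlap no other risen one (median log2 change 1.53, all 1.57). Reads past gene ends and effects of the siPOOL at this locus, direct or off target, were not tested.

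Of genes called in both, 80.3% moved with the siPOOL as at 15 days and 69.2% as at 6 months (56.6% without 6-month replicate 3). The 4 sets changed against day 0 did not pass with an estimated correlation (p = 0.155 to 0.368). The 200 risen at 6 months with the smallest p did (0.0442). Depth stays open, since only the knockdown was thinned to equal totals: 81.0% of 483 genes then moved as at 15 days. Without the androgen and cell cycle lists, 79.7% of 512 genes moved as at 15 days. The lists held 15 of the 527, too few to test an androgen or cell cycle cause. Androgen and cell cycle genes outside the lists stay open. Effects of the siPOOL on genes other than PROCA11 stay open, since only 1 siPOOL was used.

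Libraries of 2 groups can be split in 10 ways, so the real split cannot fall under a share of 0.1. The real split called 2667 against at most 1 (15 days), 4380 against at most 0 (1 month), 11958 against at most 0 (3 months), 3557 against at most 66 (6 months), 1176 against at most 972 (6 months vs 15 days) and 3699 against at most 0 (the siPOOL) in the other splits, so 1 of 10 splits reached the real count. For 1 month against 15 days and 3 months against 1 month, all 10 splits gave 0. For 6 months against 3 months, 2 of 10 did: the split of 3-month replicate 1 and 6-month replicates 1 and 2 from the rest called 5439 genes against 968, which points to structure among the libraries other than time. For all 5 times, 1 of 60 splits reached 8168 (highest other 423).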
